A study of Mus musculus with 6 samples.

How the data were processed

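Corneas of wildtype mice and of mice heterozygous for a Pax6 mutation, all aged 20 weeks, were profiled by RNA-seq, with 3 libraries per genotype. Per the labels' protocols, total RNA was extracted with a column kit, libraries were made with a stranded total RNA kit for very small inputs, and paired reads of 100 nucleotides were sequenced. Per the submitters' processing notes, Trim Galore, HISAT2, SAMtools, HTSeq and edgeR were used with the mouse build GRCm38; versions, settings and the strand option of the counting are not given in the sources used here. The deposited files hold raw counts of read pairs per Ensembl gene as HTSeq writes them, 1 file per library, with no normalization by the authors.

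Each file listed 55421 genes and 5 summary lines. The summary lines were left out of library sizes and tests. Over all libraries they held 30.1% of the lines' total as not aligned, 16.3% in no feature, 3.50% not uniquely aligned, 2.75% of low alignment quality and 0.679% ambiguous. Read pairs that align to several places stand in a summary line of their own. Gene names, positions and exons came from GENCODE release M21, which is on the same build; 55240 of the 55421 IDs matched after version numbers were removed. Gene counts were 16858005 to 21846406 per library. The most abundant gene, the small structural RNA gene Gm23935, took 13.4% to 16.2% of the gene counts of each library. At this depth a count of 0 over the 3 libraries of a group allows 3 counts, equal to 0.0556 CPM in wildtype and 0.0530 CPM in mutant; such floors cover counting error only, since molecules were not tagged.

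Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 15209, and libraries were scaled by TMM. The genotypes were compared with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, with genotype as the only term. Values per library are CPM, counts scaled by the library total and its TMM factor, and log2 fold changes are mutant minus wildtype with their standard error. Where all libraries of a group had 0 counts, the fold is a lower bound against 3 counts over the group. Each library was counted as a separate replicate because the series design names them biological replicates. Pairs of libraries of 1 group differed by 19.6 to 59.6 times the sampling noise (chi-square per degree of freedom), which separate preparations of the same RNA could also do.

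Before the data were examined, 43 gene lists were fixed from general knowledge of the cornea, its neighbouring tissues and the pathways of interest. Of these, 41 had at least 3 tested members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The counts of list members past the threshold are given over all genes and adjusted over the list alone.

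The named genes were also fixed by rule. Among genes past adjusted p 0.05 with an official symbol, at least 5 CPM in the higher group and no overlap of the groups, they are the 10 with the largest log2 fold change in each direction and, where not among them, the 3 with the smallest p, besides Pax6 and Krt12. Each list described contributes up to 4 members with the smallest p and any member that moved against the list. Slurp1, Serpinf1 and Gsto1 fall outside the rule and were named after their values were seen, to complete small counts. Some genes that the rule would name are not reported here. Overlaps of annotated exons with those of other genes were looked up for the genes and list members that are named, and the counts of those with an overlap are given as uncertain. Close copies were considered from general knowledge only, for Serpinb3a, Cyp4a12a and Dsg1a.

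The scripts were tested on simulated data for this comparison, 5 sets of counts for 15209 genes with 200 genes changed. Of genes changed 2-fold, 23.6% were called, and of genes changed 4-fold, 58.2%. False calls were 7.71% of all calls. Far fewer genes were changed than the 1529 called in the data, and no simulated library was set apart from its group. These rates therefore need not hold for the data. A shifted list of 20 genes was called by camera in all 5 sets, and 0 of 200 unshifted lists were. The simulated genes varied independently of each other, so these sets cannot show how often camera calls lists whose members vary together.

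The alternatives were RLE, upper-quartile and no composition factors, DESeq2 1.42.0, limma-voom with and without sample quality weights, no low-count filter, a filter of 1 CPM in 3 libraries, removal of mitochondrial and structural RNA genes, sex as a covariate, removal of a GC and length trend by loess (span 0.5), an adjusted p of 0.01, a log2 fold limit of 1, and leaving out each library. Leaving out mutant replicate 1 and wildtype replicate 1 together was added after the data were seen, as were the counts of list members and the signs of list medians under the alternatives. The low-count filter was run anew for each set of libraries, so the number of measured list members can differ. The labels give no batch, litter or sex.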

Results

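RNA was sequenced from corneas of mice aged 20 weeks, in 3 libraries from wildtype animals and 3 from animals heterozygous for a mutation of Pax6. Pax6 encodes a paired-box transcription factor required for eye development and for the identity of the corneal epithelium, and loss of one copy underlies aniridia and its corneal disease, aniridia-related keratopathy. The series design describes the 3 libraries of each genotype as biological replicates, and the labels do not name the mutant allele. The mutant libraries, M1 to M3, held 16858005, 17804769 and 21846406 counts in genes and the wildtype libraries, W1 to W3, 18940934, 17033330 and 18152167; 18486 to 22456 genes had at least 1 count. The comparison asked which transcripts differed between mutant and wildtype corneas.

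Pax6 RNA was lower in every mutant library than in every wildtype library. The mutant libraries held 7411, 7093 and 7914 Pax6 counts and the wildtype libraries 14970, 13141 and 14465. After normalization this was 401 ± 49.1 CPM (SD, n = 3) in mutant and 790 ± 53.5 CPM (SD, n = 3) in wildtype corneas. The log2 fold change of Pax6 was -0.98 ± 0.14 (SE), a 1.97-fold lower level, with an adjusted p of 0.0042 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Pax6 (ENSMUSG00000027168) lies on chromosome 2 from 105668900 to 105697364 on the plus strand of GRCm38. No exon of another annotated gene overlaps its exons. Counts cover its annotated exons as a whole and do not separate the mutant from the wildtype allele. Krt12 (ENSMUSG00000020912), the keratin of differentiated corneal epithelium, lies on chromosome 11 from 99415666 to 99422259 on the minus strand and fell 3.52-fold, from 18455 ± 3233 CPM to 5237 ± 1673 CPM (SD, n = 3 each). Its counts are uncertain because a gene on the opposite strand overlaps its exons.

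**Figure D1:**
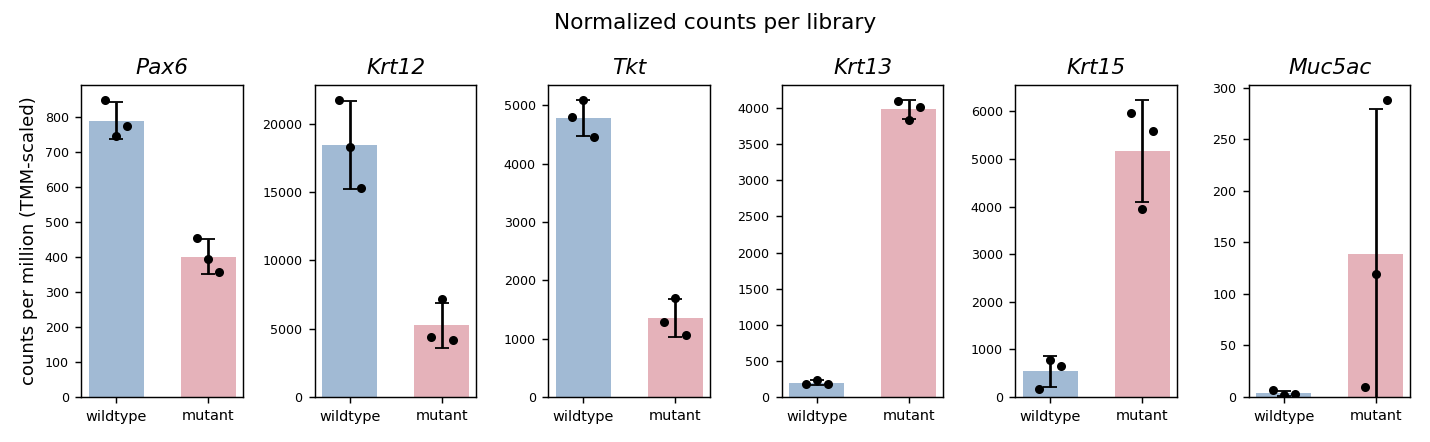
Normalized counts (CPM) of 6 genes in each genotype. Bars give the mean, error bars the SD over 3 libraries and points the single libraries, and each panel has its own axis from 0. Pax6, Krt12 and Tkt were lower and Krt13, Krt15 and Muc5ac higher in all 3 mutant libraries, with Muc5ac ranging from 9.86 to 288 CPM between them.

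Of 15209 genes tested, 850 were higher and 679 lower in mutant corneas. The median called gene was 3.11-fold higher or 2.02-fold lower, and changes of 4-fold or more were found for 329 higher and 96 lower genes. In 1527 of the 1529 called genes the mutant and wildtype libraries did not overlap; over all tested genes this held for 31.9%, where chance alone gives 10%. The number of higher genes was 455 without M1, 455 without M2, 340 without M3, 574 without W2 and 542 without W3, but 1227 without W1. The number of lower genes was 380, 351 and 271 without M1, M2 and M3, 417 without W2 and 474 without W3, but 847 without W1. Fewer libraries weaken the test, so a lost call does not by itself show the influence of the library left out. M1 was the only female library by its Xist and Y-linked counts, and W1 lay apart from all others on the first principal component, which held 50.0% of the variance.

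**Figure D2:**
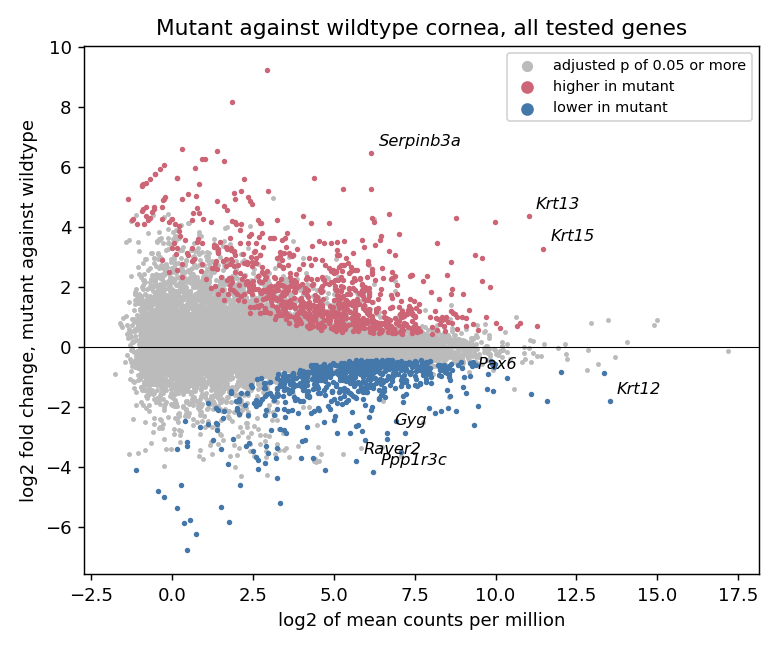
Log2 fold change of each tested gene, mutant against wildtype, by the log2 of its mean CPM over both groups. Each point is a gene, coloured where it passed an adjusted p of 0.05; genes with 0 counts in every library of a group are drawn at their bound. The 850 higher genes reach larger changes than the 679 lower ones.

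Among the higher genes chosen by rule, Itgae, the integrin alpha E chain of intraepithelial lymphocytes, had no count in any wildtype library and 5.21 ± 0.946 CPM (SD, n = 3) in mutant corneas, at least 92.8-fold higher against a floor of 3 counts over the wildtype libraries. Il18rap and Il18r1, the chains of the interleukin-18 receptor, rose by 8.16 ± 0.96 and 2.94 ± 0.14 on the log2 scale (± SE), and the decoy interleukin-1 receptor Il1r2 by 5.62 ± 0.58. These 3 receptor genes lie in the same region of chromosome 1, where Il1r2 starts at 40074079, Il18r1 at 40465552 and Il18rap at 40515362. Il1r2 ends at 40125231, so it does not adjoin the other genes. The wildtype mean of Il18rap, 0.0189 CPM, lay under the wildtype floor of 0.0556 CPM, so the size of its rise is uncertain. Serpinb3a rose from 1.60 ± 0.780 CPM to 142 ± 42.9 CPM (SD, n = 3), and Serpinb2, the plasminogen activator inhibitor 2, by 6.20 ± 1.10 on the log2 scale. Muc5ac, the gel-forming mucin of goblet cells, rose by 5.27 ± 1.11 and Slc26a9, an anion transporter, by 5.20 ± 1.23. Tnfaip2, the kallikrein protease Klk8 and the calcium-binding protein Ocm rose by 5.27 ± 0.69, 5.14 ± 0.60 and 5.58 ± 0.75. Krt13, a keratin of non-keratinized mucosal epithelium, had the smallest p among the higher genes (adjusted p = 0.00011, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), at 3986 ± 131 CPM against 196 ± 37.0 CPM (SD, n = 3). The peptidylarginine deiminase Padi1 rose 17.7-fold. Calls that ended with 1 library left out, with the adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, were of Serpinb2 without M3 (0.067), of Muc5ac without M2 (0.063), M3 (0.073), W2 (0.088) or W3 (0.070), of Slc26a9 without M1 (0.071), M2 (0.094), M3 (0.16), W2 (0.082) or W3 (0.055). Serpinb3a has near-identical relatives beside it and Serpinb2 shares exon sequence with Serpinb10, so their counts are uncertain, as are those of Klk8, Padi1 and Tnfaip2, whose exons overlap genes on the opposite strand.

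Among the lower genes chosen by rule, Ppp1r3c, which targets protein phosphatase 1 to glycogen, fell from 142 ± 10.3 CPM to 7.77 ± 3.57 CPM (SD, n = 3), and Gyg, the glycogenin that primes glycogen synthesis, from 175 ± 9.69 CPM to 24.1 ± 3.45 CPM. Raver2 fell 14.0-fold (adjusted p = 0.00011, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the receptor tyrosine phosphatase Ptprd 5.04-fold. Among the genes chosen by rule, the largest decreases by fold were of Golga7b (-5.85 ± 1.13 on the log2 scale, ± SE), Anks1b (-5.21 ± 0.61), the receptor tyrosine kinase Alk (-4.60 ± 0.65) and the fatty acid hydroxylase Cyp4a12a (-4.37 ± 0.47). Dapl1, Phyhipl and Glb1l2 fell 17.5-fold, 16.8-fold and 14.9-fold, and Syt7, a calcium sensor of exocytosis, 14.6-fold. With a single library left out, the adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was above the threshold for Golga7b without M1 (0.053) or M3 (0.057). Cyp4a12a has a near-identical copy that could share its reads. Exons of Raver2, Ptprd, Phyhipl, Glb1l2 and Syt7 overlap those of genes on the opposite strand, and their counts are uncertain because the strand setting of the counting is not given in the sources used here.

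Genes of corneal epithelial differentiation were lower and those of conjunctival and goblet epithelium higher in mutant corneas. Of 17 measured corneal epithelial genes 5 fell and 1 rose, and adjusted over the list alone 9 fell and 3 rose. Transketolase (Tkt), an abundant corneal crystallin, fell 3.55-fold to 1347 ± 323 CPM (SD, n = 3), and Upk1b 2.30-fold. Krt12 and the secreted protein Slurp1 were also among the 5, and Krt14, a keratin of basal cells, rose 4.01-fold against them. The list was lower by camera (adjusted p = 0.0069; adjusted p = 0.53 with an estimated correlation). Without W1 its camera adjusted p was 0.053 (0.00011 to 0.53 over all alternatives), with 9 members lower and 2 higher. The call of Slurp1 was lost without M1 (0.094), M3 (0.069) or W2 (0.069), adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 13 conjunctival and goblet genes 8 rose and none fell, 10 adjusted over the list alone, with a median log2 fold change of 2.40. Krt4 rose from 108 ± 62.5 CPM to 1931 ± 550 CPM (SD, n = 3) and Krt19 from 115 ± 26.5 CPM to 604 ± 49.2 CPM, while Krt7 rose by 2.34 ± 0.27 on the log2 scale. This list had a camera adjusted p of 7.0e-08, and an adjusted p = 0.17 with an estimated correlation. Its count was 5 without M3. Over the 18 alternative fits 4 to 9 corneal epithelial genes fell and 1 to 3 rose, and 5 to 12 conjunctival genes rose. The counts of Krt7 and Slurp1, whose exons overlap genes on the opposite strand, and of Tkt, which overlaps a microRNA gene, are uncertain.

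Among 10 epidermal and cornified envelope genes 4 rose and none fell, also 4 adjusted over the list alone. They were Krt17, a keratin of stressed epithelium, which rose by 3.77 ± 0.36 on the log2 scale (± SE), Sbsn by 2.32 ± 0.48, Sprr1a by 2.26 ± 0.56 and Krt6b by 0.69 ± 0.13. The camera adjusted p was 0.012, and the adjusted p = 0.49 with an estimated correlation. Without W3 the list was not called by camera (adjusted p = 0.094; 0.00023 to 0.49 over all alternatives). The count of 4 was 2 without M1 and 1 without M2, M3 or W3. Of 15 limbal progenitor genes, those of the stem cell niche at the corneal rim, 4 rose and 1 fell, with 4 and 2 adjusted over the list alone. Krt15 rose from 535 ± 322 CPM to 5167 ± 1077 CPM (SD, n = 3), Cebpd by 2.71 ± 0.28, Ifitm3 by 2.10 ± 0.22 and Cdh3 by 1.41 ± 0.24, while Lrig1 fell by 0.53 ± 0.11. The limbal list as a whole was not called (camera adjusted p = 0.61), and its median log2 fold change of 0.03 was below 0 in 6 of 18 alternative fits, at -0.0069 with upper-quartile factors. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p passed no longer for Krt6b without M2 (0.067), M3 (0.11) or W3 (0.065), for Sbsn without M1 (0.084), M2 (0.067), M3 (0.083) or W3 (0.057), for Sprr1a without M1 (0.13), M2 (0.069), M3 (0.13), W2 (0.096) or W3 (0.099). The same held for Lrig1 without M1 (0.073), M2 (0.066), M3 (0.11), W2 (0.064) or W3 (0.065). Of 29 genes of cell adhesion junctions 7 fell and none rose, with 10 and 2 adjusted over the list alone. The desmosomal cadherins Dsc3 and Dsg1a fell by 1.49 ± 0.12 and 2.04 ± 0.27, and the anchoring collagens Col17a1 and Col7a1 by 1.56 ± 0.17 and 1.06 ± 0.15. The junction list had a camera adjusted p of 0.0021 and an adjusted p = 0.57 with an estimated correlation. Its count was 4 without M2 or M3, and its camera adjusted p was 0.057 without W1 (7.4e-06 to 0.57 over all alternatives), where 2 members rose. In the alternative fits 1 to 6 epidermal, 4 to 6 limbal and 0 to 2 junction genes rose, and 0 to 3 limbal and 4 to 10 junction genes fell. Dsg1a has close relatives that could share its reads. Sbsn shares exon sequence with Tmem147os on its own strand and Col7a1 with a microRNA gene, and exons of Cebpd, Krt6b and Lrig1 overlap genes on the opposite strand, so the counts of these genes are uncertain.

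Immune cell genes were higher in mutant corneas. Of 15 macrophage genes 8 rose and none fell, with 10 adjusted over the list alone and a median log2 fold change of 2.30. Ptprc, the CD45 antigen of all leukocytes, rose by 4.13 ± 0.37 on the log2 scale (± SE), Laptm5 by 2.80 ± 0.42, the lipopolysaccharide co-receptor Cd14 by 2.24 ± 0.32 and the integrin Itgam by 1.58 ± 0.23. The macrophage list had a camera adjusted p of 5.9e-08 and an adjusted p = 0.17 with an estimated correlation. Its count was 4 without M1 or M3, and 5 of 16 measured without M2 or W3. Of 9 dendritic cell and MHC class II genes 3 rose, with 5 adjusted over the list alone: Cd74, the invariant chain, by 3.07 ± 0.35, H2-Ab1 by 2.84 ± 0.35 and Itgax by 4.65 ± 0.99 (camera adjusted p = 3.5e-05; adjusted p = 0.33 with an estimated correlation). Of 3 neutrophil genes Ltf and Csf3r rose, by 4.30 ± 0.55 and 3.27 ± 0.86, and 3 rose adjusted over the list alone (camera adjusted p = 0.015; adjusted p = 0.49 with an estimated correlation). Ltf encodes lactoferrin, also a product of glands. Of 4 lymphocyte genes Cd4 and Il2rb rose, by 5.47 ± 1.28 and 4.63 ± 1.22, with 3 adjusted over the list alone (camera adjusted p = 0.0020; adjusted p = 0.31 with an estimated correlation). Of 18 listed lymphocyte genes 4 were measured, at 0.378 CPM or less in wildtype, and of 13 listed neutrophil genes 3 were. Genes this low in wildtype pass the low-count filter only with the help of high mutant libraries. The filter thus favoured a rise in the lymphocyte list, and its signs and camera result are no independent evidence of one. The other immune lists share this limit in part. In wildtype, 1 of 3 neutrophil, 1 of 9 dendritic and 4 of 15 macrophage genes reached 5 CPM. The second most abundant neutrophil gene stood at 0.624 CPM and the second dendritic gene at 1.23 CPM. Their camera results may thus also owe something to the filter. The lymphocyte count was 0 of 4 measured without M2 or M3, 0 of 6 without M1 or W2, 1 of 6 without W3 and 4 of 6 without W1. The neutrophil count was 1 of 3 measured without M2 or M3, 1 of 5 without M1, W2 or W3 and 3 of 5 without W1. Alternative fits called 4 to 12 macrophage and 2 to 5 dendritic genes higher, 1 to 5 neutrophil genes of 3 to 10 measured and 0 to 5 lymphocyte genes of 2 to 18 measured. Calls that ended with 1 library left out, with the adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, were of Csf3r without M1 (0.079), M2 (0.18), M3 (0.14), W2 (0.071) or W3 (0.11), of Cd4 without M1 (0.11), M2 (0.071), M3 (0.11), W2 (0.061) or W3 (0.083), of Il2rb without M1 (0.088), M2 (0.16), M3 (0.17) or W2 (0.11). Likewise affected were the calls of Itgax without M1 (0.067), M2 (0.0998), M3 (0.10) or W2 (0.075). Itgam shares exon sequence with another gene on its strand and Cd74 with a microRNA gene, which makes their counts uncertain.

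Of 11 cytokine genes 4 rose, and adjusted over the list alone 7 rose and 1 fell. Il1rn, the interleukin-1 receptor antagonist, rose by 3.22 ± 0.25 on the log2 scale (± SE), the alarmin Il33 by 3.46 ± 0.30, lipocalin Lcn2 by 3.70 ± 0.84 and Cxcl16 by 1.63 ± 0.38 (camera adjusted p = 0.0026; adjusted p = 0.49 with an estimated correlation). This count was 2 without M2 or M3 and 2 of 15 measured without W2 or W3. Alternative fits called 2 to 12 cytokine genes higher, of 10 to 23 measured, and 0 to 1 lower. Of 19 interferon response genes Gbp2 and Gbp3 rose, by 1.28 ± 0.19 and 1.51 ± 0.35, the same number adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.49 with an estimated correlation). Without W3 the interferon list was not called by camera (adjusted p = 0.11; 0.0036 to 0.49 over all alternatives), and 1 to 3 members rose in the alternative fits. With a single library left out, the adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was above the threshold for Lcn2 without M2 (0.096), M3 (0.11), W2 (0.10) or W3 (0.067), for Cxcl16 without M2 (0.12), M3 (0.13), W2 (0.088) or W3 (0.056), for Gbp3 without M1 (0.11), M2 (0.11), M3 (0.10) or W3 (0.082). Of 2 mast cell genes Kit, which melanocytes and epithelia also express, fell by 1.09 ± 0.16, also adjusted over the list alone. Opposite-strand genes overlap exons of Cxcl16 and Gbp2, and their counts are uncertain.

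Genes of the corneal stroma were higher in mutant corneas. Of 19 keratocyte and stromal matrix genes 13 rose and 1 fell, with 15 and 1 adjusted over the list alone, and their median log2 fold change was 2.44. The glycosyltransferase B3gnt7 rose by 3.11 ± 0.50 on the log2 scale (± SE), Angptl7 by 3.49 ± 0.60, the proteoglycan Bgn by 2.49 ± 0.43 and the collagen Col12a1 by 2.17 ± 0.41, whereas Aldh1a1, a corneal aldehyde dehydrogenase, fell by 1.46 ± 0.28. The camera adjusted p was 1.1e-05, and the adjusted p = 0.49 with an estimated correlation. The count of 13 was 8 without M1, 3 without M2, 7 without W2 or with the quality weights of limma-voom, and 5 without W3, and over the 18 alternative fits 3 to 17. Of 18 myofibroblast and fibrosis genes 3 rose and 1 fell, with 9 and 1 adjusted over the list alone: the matrix protein Tnc rose by 3.39 ± 0.32, the collagen cross-linker Lox by 2.80 ± 0.42 and Ccn2 by 2.17 ± 0.46, and Tgfbi fell by 1.40 ± 0.17 (camera adjusted p = 0.0020; adjusted p = 0.53 with an estimated correlation). The count of 3 was 9 with DESeq2, 7 with limma-voom, 13 of 20 measured with no low-count filter, 7 of 20 without W1 and 6 of 19 without W2. Of 13 matrix metalloproteinase and inhibitor genes Adam8, Mmp2 and Timp2 rose, by 3.62 ± 0.42, 2.75 ± 0.48 and 1.91 ± 0.38, with 5 adjusted over the list alone (camera adjusted p = 0.0021; adjusted p = 0.49 with an estimated correlation). Of 11 corneal endothelium genes 2 rose, among them the water channel Aqp1 by 1.54 ± 0.32, with 3 adjusted over the list alone (camera adjusted p = 0.0093; adjusted p = 0.49 with an estimated correlation). That count was 4 without W2 and 1 without any 1 mutant library or W3, and without W3 camera did not call the list (adjusted p = 0.050; 0.00043 to 0.49 over all alternatives). In the alternative fits 2 to 6 metalloproteinase and inhibitor genes and 1 to 6 endothelium genes rose. The call of Aldh1a1 was lost without M2 (0.074), M3 (0.073) or W2 (0.054), adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. So were those of Ccn2 without M1 (0.078), M3 (0.094) or W3 (0.059), and of Timp2 without M1 (0.065), M3 (0.057) or W3 (0.052). Calls also ended for Col12a1 without M2 (0.050), for Aqp1 without M1 (0.079), M2 (0.052), M3 (0.074) or W3 (0.062). Uncertain through overlaps with genes on the opposite strand are the counts of Adam8, B3gnt7, Ccn2, Lox and Tnc.

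Of 17 blood vessel endothelium genes none passed edgeR's quasi-likelihood test, also adjusted over the list alone; 3 had an unadjusted p under 0.05, and 3 were called by DESeq2, 1 by limma-voom and 10 with no low-count filter. All 17 estimates were positive, with a median log2 fold change of 1.66 (camera adjusted p = 0.0013; adjusted p = 0.64 with an estimated correlation). W1 held these genes at -2.34 against the wildtype mean on the log2 scale and the other wildtype libraries at 1.27 and 1.07, beside 1.76 to 3.01 in the mutant libraries. Without W1, 3 vessel genes rose and the median was 1.17; without both M1 and W1, an alternative chosen after the data were seen, it was 0.66, with 13 estimates positive and 4 negative. Of 17 angiogenic and anti-angiogenic factor genes 4 rose and 1 fell, with 9 and 1 adjusted over the list alone. Vegfa, the main vessel growth factor, rose by 1.26 ± 0.18 on the log2 scale (± SE), Angpt2 by 1.92 ± 0.48, and the anti-angiogenic genes Thbs2 and Serpinf1 by 3.13 ± 0.57 and 2.50 ± 0.63, while Angptl4 fell by 1.80 ± 0.32 (camera adjusted p = 0.0011; adjusted p = 0.49 with an estimated correlation). The count of 4 was 2 without M2 or W3, and 2 to 7 over the alternative fits. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p passed no longer for Angpt2 without M2 (0.14), M3 (0.19), W2 (0.12) or W3 (0.087), for Angptl4 without M1 (0.053) or M3 (0.063), for Serpinf1 without M1 (0.13), M2 (0.098), W1 (0.064), W2 (0.058) or W3 (0.12). No gene passed edgeR's test among 6 of lymphatic endothelium or 9 of pigment cells (camera adjusted p = 0.11 and 0.055), nor adjusted over the list alone; 2 and 0 had an unadjusted p under 0.05, and DESeq2 called 2 and 0, limma-voom 0 of each and edgeR with no low-count filter 3 of 7 and 6 of 9. Camera called the pigment list higher with all libraries under RLE (adjusted p = 0.047) or upper-quartile factors (0.042), limma-voom, no low-count filter or removal of the GC and length trend, and without W2 (0.0045) or W3 (0.038). Over all alternatives its adjusted p was 0.0045 to 0.76. The lymphatic list was called higher with no low-count filter.

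**Figure D3:**
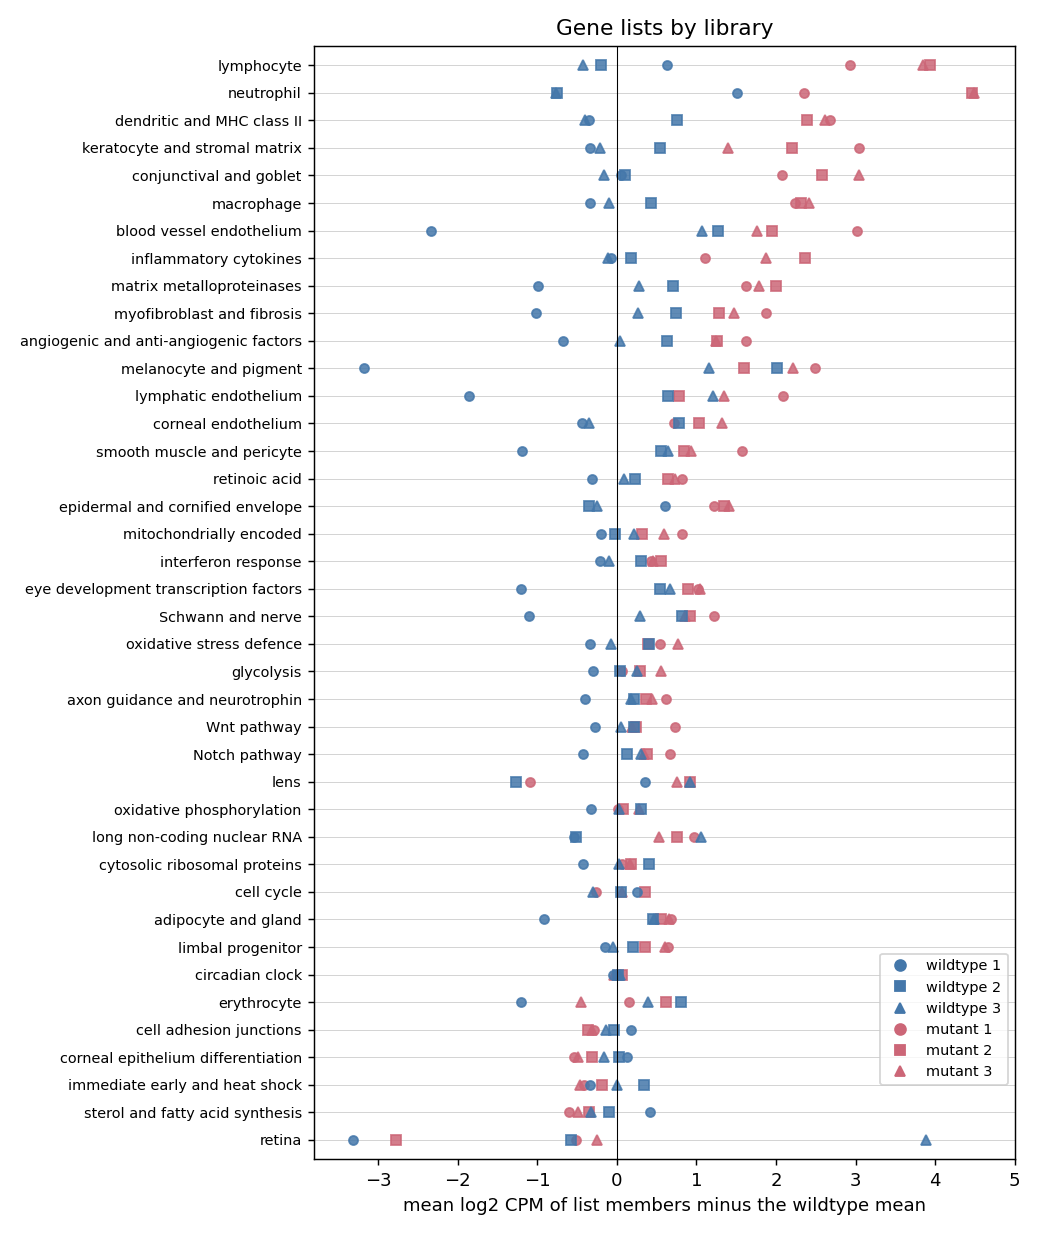
Mean log2 CPM of the tested members of each gene list in each library, minus the mean of the 3 wildtype libraries. Colours give the genotype and marker shapes the replicate; lists are ordered by their median log2 fold change, and the sex-linked list is left out. The 3 mutant libraries lay above all wildtype libraries for the conjunctival, macrophage and keratocyte lists, while W1 lay at -3.17 for pigment genes.

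Sterol and fatty acid synthesis genes were lower in mutant corneas: 7 of 20 fell and none rose, with 11 fallen adjusted over the list alone. Srebf1, the transcription factor of lipid synthesis, fell by 0.95 ± 0.15 on the log2 scale (± SE) and Hmgcs1, an enzyme of cholesterol synthesis, by 1.21 ± 0.20 (camera adjusted p = 0.00045; adjusted p = 0.64 with an estimated correlation). The count of 7 was 2, 3 and 1 without M1, M2 and M3 and 4 without W2, and 1 to 12 over the alternative fits; without W1, 2 members rose. Without both M1 and W1, an alternative chosen after the data were seen, camera did not call the list (adjusted p = 0.089; 3.4e-06 to 0.64 over all alternatives). Of 19 immediate early and heat shock genes 3 fell and 1 rose, with 7 and 1 adjusted over the list alone: Ier2, Hspb1 and Fos fell by 1.01 ± 0.16, 0.98 ± 0.17 and 1.41 ± 0.27, and Hspa8 rose by 0.69 ± 0.16 (camera adjusted p = 0.0031; adjusted p = 0.49 with an estimated correlation). Over the alternative fits 1 to 9 fell. With upper-quartile factors 7 fell, 6 with library totals only, and 5 without mitochondrial and structural RNA genes or with the GC and length trend removed. Of 20 measured, 8 fell without W1, 5 without W3 and 1 without M3, and without W2 camera did not call the list (adjusted p = 0.066; 0.00031 to 0.49 over all alternatives). Of 12 mitochondrially encoded genes 3 rose, with 7 adjusted over the list alone: mt-Co1 by 0.79 ± 0.17, mt-Cytb by 0.78 ± 0.18 and mt-Nd1 by 0.59 ± 0.14 (camera adjusted p = 0.0020; adjusted p = 0.56 with an estimated correlation). All genes of the mitochondrial chromosome together took 6.22 ± 0.777% of the gene counts of mutant and 3.44 ± 0.957% of those of wildtype libraries (SD, n = 3). In wildtype the ribosomal RNAs mt-Rnr2, at 22709 CPM, and mt-Rnr1, at 7939 CPM, were the most abundant members of the list. The count of 3 was 0 without M1, M3 or W2, with sex as a covariate or with the GC and length trend removed, 1 without W3, 5 without W1 and at most 7 in an alternative fit. Calls that ended with 1 library left out, with the adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, were of Hmgcs1 without M3 (0.052). Further such calls were those of Hspb1 without M3 (0.059), of Fos without M1 (0.068), M2 (0.053) or M3 (0.077), of Hspa8 without M2 (0.12), M3 (0.15), W2 (0.085) or W3 (0.11). The same held for mt-Co1 without M1 (0.089), M2 (0.052), M3 (0.085) or W2 (0.088), for mt-Cytb without M1 (0.12), M3 (0.13), W2 (0.11) or W3 (0.053), for mt-Nd1 without M1 (0.13), M3 (0.16), W2 (0.12) or W3 (0.068). No gene passed edgeR's test among 22 of the cell cycle, 20 of glycolysis, 22 of oxidative phosphorylation or 30 of cytosolic ribosomal proteins, also adjusted over the list alone, and camera called none of these lists (adjusted p = 0.95, 0.29, 0.47 and 0.51). At an unadjusted p under 0.05 there were 1, 4, 2 and 1 such genes, DESeq2 called 0, 2, 1 and 1, and limma-voom 0 in each. With its quality weights limma-voom called 2 glycolysis genes. Without both M1 and W1, 2 glycolysis genes rose and 1 fell, and 1 cell cycle gene rose. With no low-count filter 3 glycolysis genes rose and 1 fell. Without W2 camera called the ribosomal list higher (adjusted p = 0.0069; 0.0069 to 0.92 over all alternatives). Without W1 it pointed lower (adjusted p = 0.28), with a median log2 fold change of -0.12 against 0.09 as reported. Exons of Hmgcs1, Srebf1 and mt-Co1 overlap genes on the opposite strand and those of Srebf1, Hspa8 and mt-Nd1 small RNA genes on their own strand, so these counts are uncertain.

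All 19 lists called by camera, 15 higher and 4 lower, lost their call with an estimated correlation. The test by fry, which asks whether the genes of a list move on balance one way, called 10 of 41 lists, and 27 when a change in either direction counts; fry does not compare a list with other genes.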

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

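The test of read numbers in W1 was planned before its result was seen, as were the splits of the samples; the other tests of explanations below, and their values with 1 library left out, were chosen after the results they bear on had been seen.

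Xist, the long RNA expressed from the inactive X chromosome, was left untested by the low-count filter and had 18628 counts in M1 against at most 12 in each other library. The same library held 0 counts of Ddx3y, Uty, Eif2s3y and Kdm5d, so it came from a female and the other 5 libraries from males. The lines that HTSeq sets aside for low alignment quality took 2.78% of the mutant and 2.72% of the wildtype libraries' lines on average. Every mutant library lay above every wildtype library, by little (2.749% in M2 against 2.737% in W3). All 5 summary lines were screened for such a separation, which chance alone gives in 10% of cases for 3 against 3 libraries.

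W1 stood apart from W2 and W3 and detected 18486 genes. Fewer reads do not account for this, since W1 held 18940934 gene counts, the most of the 3 wildtype libraries; with all libraries thinned to the smallest total it detected 0.868 times the mean of the other 2. The vessel, lymphatic, pigment and smooth muscle lists were all lower in it by at least 1.78 on the log2 scale (-1.784 for smooth muscle), and the pigment list was 27.0-fold lower. Of these 4 lists only smooth muscle shares genes with another list, 2 of them; 5 of 17 vessel, 3 of 6 lymphatic, 6 of 9 pigment and 8 of 10 smooth muscle genes reached 5 CPM in wildtype corneas, led by Flt1 at 16.3, Reln at 42.7, Dct at 110 and Notch3 at 532 CPM (overlapping genes make Reln and Notch3 uncertain). A candidate explanation, less vessel- and pigment-bearing tissue around this cornea, was tested only after the fact on the lists that prompted it and stays open; no biological explanation was tested, as the design names none for a single wildtype library.

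The mean of the conjunctival and goblet list lay 2.59 higher in mutant on the log2 scale against W2 and W3 alone. The pigment list lay 0.52 and the vessel list 1.07 higher in that comparison. The conjunctival difference exceeded that of the pigment list by 2.08 ± 0.53 (SE), and by 1.78 to 2.51 with 1 library left out. More pigment-bearing tissue of the same makeup as in W2 and W3 would raise both lists alike, and the values argue against that as the whole cause. The comparison cannot judge added tissue of another makeup, such as tissue richer in conjunctiva. Conjunctiva left on the mutant corneas at dissection stays open: the SD of the list over the mutant libraries was 0.931 times that of the pigment list over all libraries but W1 (0.623 to 1.30 with 1 library left out), too large to exclude it. No gene of this list is in another list, and 10 of its 13 measured members reached 5 CPM in wildtype corneas, led by Muc4 at 5832 CPM (uncertain, as its exons overlap Muc20), so a changed epithelium may also contribute.

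The keratocyte and stromal list had a median log2 fold change of 2.29 without W1, which argues against a low stromal share in that library alone. A lower epithelial share of the mutant tissue would raise stromal and endothelial genes alike. It would also lower genes of the corneal epithelium, and that part was not tested. The keratocyte difference was larger than that of the corneal endothelium list by 1.19 on the log2 scale, with a standard error of 0.66. It depended on single libraries (0.62 without M1 and 1.74 without M3). A lower epithelial share thus cannot be told apart from a change within the stroma with 3 libraries per group. A genotype effect on the stroma stays open as well; 16 of 19 keratocyte genes reached 5 CPM in wildtype, led by Col1a1 at 175 CPM, and 1 is in another list.

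The split by genotype called 1529 genes, and the highest count among the other splits of the 6 libraries into 3 and 3 was 0 genes. It was 1 of 10 splits to reach that count, and 10 splits are too few for a share under 0.05. For gene lists called by camera, 3 of the 10 splits reached 19 or more, the genotype split included. Every other split called lists too, from 7 to 23, the most with M1, M3 and W2 against the rest. A count of 19 called lists was therefore not particular to the split by genotype. Here too, 10 splits are too few for a share under 0.05. Each other split put unequal numbers of the genotypes on its sides. It thus kept part of the genotype difference and gave no baseline free of it. Mixing the genotypes also widens the spread within a side, which by itself lowers the number of genes called.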

How the results depend on the processing

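The alternative without both M1 and W1, the counts of list members and the signs of list medians were chosen after the data were seen. The Pax6 log2 fold change kept its direction and an adjusted p under 0.05 in every alternative fit, with values from -1.07 to -0.91; as reported it lies under the log2 fold limit of 1. Higher and lower genes were 1325 and 1033 with DESeq2, which left 51 genes without an adjusted p, and 1588 and 1137 with no low-count filter, where 28717 genes were tested. With sex as a covariate they were 471 and 376; since M1 is the only female, this fit leaves that library no say in the genotype effect. At an adjusted p of 0.01 they were 307 and 261, and 638 higher and 343 lower genes changed by at least 1 on the log2 scale. Leaving out 1 library gave 340 to 1227 higher and 271 to 847 lower genes, the lowest without M3 and the highest without W1, whose quality weight in limma-voom was 0.304. Fewer libraries also weaken the test. No gene called as reported was called in the opposite direction by any alternative. Without both M1 and W1, 1026 were higher and 754 lower, and camera lost its calls of the corneal epithelium (adjusted p = 0.15), interferon (0.057), junction (0.073) and sterol (0.089) lists and gained those of the retina list (0.0067) and of the skeletal muscle list (0.045), which was too small for camera as reported. Among the wildtype libraries W3 held the retina and skeletal muscle lists highest, at 3.88 and 2.47 against the wildtype mean on the log2 scale. The cause of the lost and gained calls was not tested.

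Camera called 19 lists as reported, 0 with an estimated correlation, where the lowest adjusted p was 0.17, and fry called 10, among them the limbal and retinoic acid lists that camera did not call; camera called 17 to 22 when 1 library was left out. With all libraries it gained the pigment list with RLE (adjusted p = 0.047) or upper-quartile factors (0.042), with limma-voom and with the GC and length trend removed. It gained the pigment, lymphatic, smooth muscle, Schwann and skeletal muscle lists with no low-count filter and the retina list with DESeq2 or quality weights, and lost the interferon list with DESeq2. The largest shift of the median of all genes was -0.035 on the log2 scale, with upper-quartile factors. In 18 alternative fits the median of the limbal list changed sign in 6, and camera's direction of the uncalled lens and erythrocyte lists in 11 and 7; other uncalled lists changed sign in fewer, and no list called as reported did. Of 43 counts of list members above 0, those over 1.5 times larger were 15 with DESeq2, 23 with no low-count filter, 6 with limma-voom, 9 with its quality weights and 10 without W1. Over 1.5 times smaller were 21 with sex as a covariate, 13 to 28 without any other single library, 2 with limma-voom, 3 each with its quality weights and without both M1 and W1, and 1 each with the GC and length trend removed and without mitochondrial and structural RNA genes. Without both M1 and W1, 10 were larger, with the GC and length trend removed 3, and with any other alternative at most 2. Of the genes named by fold or p, Tnfaip2, Muc5ac and Slc26a9 were not called by limma-voom, and Slc26a9 and Golga7b not with sex as a covariate. Genes named as list members are outside this tally, and they also lost calls. With sex as a covariate, 7 of the 43 counts of list members fell to 0, among them the lymphocyte genes that rose and the limbal gene that fell. No paired analysis was possible because the labels give no pairing. Depth limits genes near the floor of 3 counts, such as Itgae and Il18rap in wildtype.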

Other observations

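The counts of list members under the alternatives below were chosen after the data were seen. Transcription factor, signalling and clock genes changed in both directions. Of 17 circadian clock genes 3 rose and 3 fell, with 3 and 4 adjusted over the list alone. The clock activator Arntl fell by 1.90 ± 0.25 on the log2 scale (± SE), from 60.3 ± 5.84 CPM to 16.2 ± 5.88 CPM (SD, n = 3), Cry2 fell by 0.87 ± 0.13 and Hlf by 0.96 ± 0.16, while Per1, Per2 and Npas2 rose by 1.02 ± 0.16, 0.64 ± 0.14 and 0.99 ± 0.24. The labels do not give the time of day of sampling. The count of 3 higher clock genes was 1 without any 1 library but W1. Of 20 eye development transcription factors Pitx1 and Maf rose, by 4.35 ± 0.52 and 1.70 ± 0.31, and 3 fell, among them Tfap2a by 0.75 ± 0.15 and Dach1 by 0.64 ± 0.14, the same numbers adjusted over the list alone; the 2 higher were 1 and the 3 lower 1 without M2 or M3, and 1 was higher without M1. Of 15 retinoic acid genes 4 rose and 2 fell, with 5 and 2 adjusted over the list alone: the retinol receptor Stra6 rose by 2.57 ± 0.35, Crabp2 by 2.16 ± 0.44 and Aldh1a3 by 1.16 ± 0.21, Aldh1a1 fell by 1.46 ± 0.28 and Cyp26b1 from 49.7 ± 13.6 CPM to 24.9 ± 4.93 CPM (SD, n = 3). The 4 were 1 of 16 measured without any 1 mutant library, and the 2 lower were 1 without M1 and 0 without M2, M3 or W2. With a single library left out, the adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was above the threshold for Per2 without M1 (0.070), M2 (0.10), M3 (0.12), W2 (0.071) or W3 (0.077), for Npas2 without M1 (0.10), M2 (0.061), M3 (0.083), W2 (0.12) or W3 (0.11), for Maf without M1 (0.058), M2 (0.057) or M3 (0.051). Likewise affected were the calls of Tfap2a without M1 (0.075), M2 (0.056) or M3 (0.084), of Dach1 without M2 (0.11), M3 (0.12), W2 (0.076) or W3 (0.063), of Crabp2 without M1 (0.076), M2 (0.070) or M3 (0.076). Calls also ended for Aldh1a3 without M1 (0.050), M2 (0.050), M3 (0.062) or W2 (0.054), for Aldh1a1 without M2 (0.074), M3 (0.073) or W2 (0.054). Further such calls were those of Cyp26b1 without M1 (0.073), M2 (0.090), M3 (0.12) or W2 (0.050). Over the 18 alternative fits 1 to 4 clock genes rose and 3 to 4 fell, 1 to 3 eye factors rose and 1 to 3 fell, and 1 to 6 retinoic acid genes rose and 0 to 3 fell. Pitx1, Arntl, Cry2, Maf and Tfap2a have exons that overlap genes on the opposite strand, Pitx1 also on its own strand, so their counts are uncertain.

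Of 23 Wnt genes Fzd1 and Dkk2 rose, by 1.43 ± 0.14 and 1.63 ± 0.42 on the log2 scale (± SE), Wnt7b fell 2.82-fold and Wnt3a fell by 1.65 ± 0.35, with 4 higher and 3 lower adjusted over the list alone. Each count of 2 was 1 without M1 or M2, and the 2 higher were also 1 of 24 measured without M3, W2 or W3. Of 17 Notch genes Notch3 and Jag1 fell, by 1.12 ± 0.16 and 0.73 ± 0.16, with 3 adjusted over the list alone; 1 passed without any 1 mutant library. Of 26 axon guidance and neurotrophin genes Sema3a, Slit3 and Sema3c rose, by 1.73 ± 0.23, 2.26 ± 0.40 and 2.20 ± 0.53, and Efnb1 fell by 1.02 ± 0.17, with 6 and 5 adjusted over the list alone. Without W1 these counts were 5 and 2; Efnb1 did not pass without M3, and 2 genes fell without M1. Of 22 oxidative stress genes Txnrd1, Sod3, Srxn1 and Gsto1 rose, by 1.76 ± 0.32, 2.07 ± 0.39, 0.89 ± 0.17 and 0.70 ± 0.16, and Prdx6 fell by 0.84 ± 0.15, with 10 and 4 adjusted over the list alone. The 4 were 0 without M3 and 2 without M1 or W3, and the 1 lower gene was 6 without W1 and 0 without M1 or M3. Camera called none of these lists, nor the clock, eye factor and retinoic acid lists (lowest adjusted p = 0.094, for retinoic acid); without W2 it called the oxidative stress list higher (adjusted p = 0.037; 0.037 to 0.79 over all alternatives). The call of Dkk2 was lost without M1 (0.17), M2 (0.097), M3 (0.085), W2 (0.11) or W3 (0.096), adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. So were those of Wnt3a without M1 (0.075), M2 (0.081) or M3 (0.11), and of Jag1 without M1 (0.082), M2 (0.078) or M3 (0.11). The same held for Sema3c without M1 (0.12), M2 (0.087), W2 (0.11) or W3 (0.099), for Efnb1 without M3 (0.057), for Txnrd1 without M3 (0.058) or W2 (0.052). Likewise affected were the calls of Sod3 without M3 (0.069), of Srxn1 without M1 (0.059), M3 (0.080), W2 (0.054) or W3 (0.050), of Gsto1 without M1 (0.077), M2 (0.11), M3 (0.15) or W3 (0.10). Calls also ended for Prdx6 without M1 (0.058) or M3 (0.069). Alternative fits called 1 to 6 Wnt genes higher and 1 to 3 lower, 0 to 1 Notch genes higher and 1 to 3 lower, 2 to 8 axon guidance genes higher and 0 to 4 lower, and 0 to 8 oxidative stress genes higher and 0 to 6 lower. The counts of Wnt7b and Notch3, whose exons overlap genes on the opposite strand, are uncertain.

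Markers of neighbouring tissues varied between libraries. Of 14 retina genes none passed, also adjusted over the list alone (camera adjusted p = 0.17), and their median log2 fold change was -3.36. W3 held them 3.88 above the wildtype mean on the log2 scale; without that library the median was 0.65. With no low-count filter 14 of 15 measured retina genes fell. Without W1, 5 retina genes fell and camera called the list lower (adjusted p = 0.0029; 0.0029 to 0.82 over all alternatives). Of 2 skeletal muscle genes Tnni2 fell by 1.64 ± 0.40 (± SE), with 2 adjusted over the list alone; without W1, 3 of 7 measured fell, and with no low-count filter 8 of 15. Camera tests lists of at least 3 genes and called this list lower without W1 (adjusted p = 0.010), without both M1 and W1 (0.045) and with no low-count filter (0.0073), but not without M1, M2, M3 or W2 (0.10 to 0.23). Of 10 smooth muscle and pericyte genes Abcc9 rose by 1.76 ± 0.13 and Notch3 fell, 1 each adjusted over the list alone (camera adjusted p = 0.094), and of 4 adipocyte and gland genes Aqp5, also a corneal epithelial water channel, fell by 0.85 ± 0.18, also adjusted over the list alone (camera adjusted p = 0.87). Abcc9, like Notch3, overlaps a gene on the opposite strand and is uncertain. In the alternative fits 1 to 5 smooth muscle genes rose, and 0 to 2 adipocyte and gland genes fell. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p passed no longer for Tnni2 without M1 (0.12), M2 (0.063), M3 (0.12), W1 (0.062) or W3 (0.084), for Aqp5 without M1 (0.11), M2 (0.055), M3 (0.13) or W2 (0.053). No gene passed among 6 lens, 12 Schwann and nerve, 5 erythrocyte, 5 nuclear long non-coding and 4 sex-linked genes, also adjusted over the list alone (camera adjusted p = 0.97, 0.15, 0.97, 0.58 and 0.23); without W1, 2 Schwann and nerve genes rose, and without W3, 2 of 6 measured long non-coding genes did. Without W2 camera called the Schwann list higher (adjusted p = 0.017; 0.017 to 0.69 over all alternatives). Among the retina, lens, Schwann, erythrocyte, long non-coding and sex-linked genes 3, 0, 3, 0, 1 and 0 had an unadjusted p under 0.05 by edgeR. Of these lists DESeq2 called 0, 0, 2, 0, 0 and 0 genes, and limma-voom 0 of each. With its quality weights limma-voom called 1 Schwann gene, and 1 rose without both M1 and W1. With no low-count filter 3 Schwann and 2 long non-coding genes rose and 1 long non-coding gene fell, and of the sex-linked genes 1 rose and 1 fell. The lens list had a median of 0.14 and a mean of 0.03, whereas camera pointed lower, and higher in 11 of 18 alternative fits (adjusted p = 0.32 to 0.99 over all alternatives).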
